A study of Mus musculus with 11 samples.

How the data were processed

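Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map acetylated lysine 27 of histone H3 (H3K27ac), a mark of active promoters and enhancers, and Smc1a, a subunit of the cohesin ring. The cells were sorted CD4+ CD8+ thymocytes of mice aged 6 weeks. H3K27ac was profiled in 2 wild-type (WT) and 2 Rad21-deleted (KO) libraries, and Smc1a in 2 WT libraries. Peak lists of these 6 libraries were analysed. The 5 input libraries of the series were not analysed here.

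The reads had been aligned with Bowtie 0.12.8 to the mouse build mm9, per the submitters' processing notes. Peaks carry MACS names, per the file contents, and each list holds the calls of a single library, so replicates had not been pooled. The version and settings of the peak caller, the input set against each library and any read filters are not given in the sources used here. The deposited lists give a start, an end and a score for each peak, and the score is the authors' own value from their peak caller. The lowest score was 50 or 50.01 in every list and many H3K27ac peaks were tied at or near 3100. The score was therefore used mainly to rank or filter peaks within a list. Median Smc1a scores were also compared within replicate 1. Peaks at 3100 or more were counted over the pooled H3K27ac lists, with a test stratified by list. Scores of named regions are given as deposited. Broad acetylated stretches were reported by the caller as single peaks or as several peaks, so the number of peaks also depends on how a stretch was split. The files hold no reads, so depth per library is unknown and a peak that is missing from a list is a missing call, not a measured absence of acetylation.

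Intervals were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and Jaccard indices were taken from bedtools 2.31.1. Overlapping or touching peaks of the 4 H3K27ac libraries were merged into union regions, and a library held a region if 1 of its peaks overlapped it by at least 1 bp. WT-only regions had a peak in both WT libraries and in neither KO library, and KO-only regions had the reverse. Reproducible Smc1a sites were merged regions with a peak of both Smc1a replicates. For the comparison of clustered with isolated acetylation, WT regions with a peak of both WT libraries were stitched where they lay within 12500 bp of each other. Stitched groups of at least 3 regions were called clusters, and a region with no neighbour at that distance was called isolated.

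Peak numbers and covered lengths were compared with two-sided exact permutation tests over the 4 libraries, for which the smallest possible p is 0.333. Shares of regions were compared with two-sided Fisher's exact tests, and again per chromosome with two-sided sign-flip permutation tests of the difference in share over 20 chromosomes (100000 resamples, smallest possible p 1e-05). These tests of shares treat regions or chromosomes as units, so they describe these libraries and measure the spread neither between libraries nor between mice. Only the permutation tests over the 4 libraries measure the spread between these samples. That spread may be technical, since the labels do not say whether the libraries of a group came from separate mice. Intervals on shares are Wilson 95% intervals and cover counting error only. The placement of Smc1a sites was set against 1000 circular shifts of the sites within their chromosomes, for which the smallest possible p is 0.001. No 2 libraries of the same target held an identical peak, so none repeated another library of its target.

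Interval functions and share tests were tested on simulated data. With 1259 regions in the sizes of the WT-only and KO-only classes, planted shares of 12% and 6% were called by Fisher's exact test in 97.5% of 200 simulations and by the test per chromosome in 91.5%. With equal shares of 8% the calls were 3.5% and 4%. The simulated regions were drawn independently of each other, so these rates do not cover regions that are grouped along chromosomes.

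The comparisons, their tests, the gene lists and the rule for named items were fixed before the data were examined. The rule named the 10 longest WT-only and the 10 longest KO-only regions, the 10 WT clusters with the greatest summed region length and the 5 longest reproducible Smc1a sites. Regions are given by mm9 coordinates counted from 1. No gene annotation of mm9 was used here, so regions were not assigned to genes, exons or introns and the gene lists were not tested. The alternatives tried were a stricter score threshold (the upper 75% of each list), equal numbers of peaks per list, an overlap of at least 50%, each library left out in turn, the replicate number as a block, matching on region length, stitching within 5000 or 25000 bp, merging within 1000 bp, and wider windows around regions. Crossed pairings of the 4 libraries were planned for the Jaccard index and for the counts of WT-only and KO-only regions. Crossed pairings in the other comparisons and clusters built from all 4 libraries alike were added after the planned comparisons had been seen. So were the distances between regions and the tests of neighbouring regions, bridged gaps and broad peaks.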

Results

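The series concerns cohesin and the grouping of enhancers in developing T cells. Rad21 encodes the kleisin subunit that closes the cohesin ring, and it was deleted with a Cre transgene driven by Cd4, which is active from the CD4+ CD8+ stage of T cell development. H3K27ac was mapped in 2 WT and 2 KO libraries of sorted CD4+ CD8+ thymocytes, and Smc1a in 2 WT libraries. The H3K27ac lists held 21973 peaks (WT replicate 1), 15686 peaks (WT replicate 2), 19503 peaks (KO replicate 1) and 20244 peaks (KO replicate 2). The Smc1a lists held 25484 and 17726 peaks. H3K27ac peaks were broad, with median widths of 1852 to 2164 bp per library, and Smc1a peaks were narrow, with median widths of 684 and 667 bp.

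The first comparison asked whether the extent of acetylated chromatin differed between the genotypes. WT libraries held 18829.5 ± 4445.6 H3K27ac peaks and KO libraries 19873.5 ± 524.0 (SD, n = 2 each). Called peaks covered 50.9 ± 7.56 Mb in WT and 50.1 ± 3.59 Mb in KO libraries. The spread between the WT libraries was larger than the difference between genotypes for both measures (exact permutation test, p = 1 for each). The KO minus WT difference was 1044 peaks, but 4187.5 without WT replicate 1 and -2099.5 without WT replicate 2. For covered length it was -0.820 Mb, but 4.52 Mb without WT replicate 1, 1.72 Mb without KO replicate 2, -6.16 Mb without WT replicate 2 and -3.36 Mb without KO replicate 1.

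Acetylation lay at largely shared places in both genotypes. Of 13937 regions called in both WT libraries, 12403 (89.0%) also had a peak in both KO libraries, and 569 (4.08%) had a peak in neither. The Jaccard index of covered bases was 0.670 between the WT libraries and 0.738 between the KO libraries. Between genotypes it ran from 0.637 (WT replicate 2 with KO replicate 2) to 0.723 (WT replicate 1 with KO replicate 1). The mean of the 4 pairs between genotypes was 0.676, against 0.704 within genotypes, a difference of -0.0279. Of the 3 ways to split the 4 libraries into pairs, the split by genotype was the one with a negative difference, the others giving 0.00839 and 0.0196. With 3 splits the smallest share a test can reach is 0.333, and without KO replicate 2 the difference was 0.0314.

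The next comparison asked which acetylated regions were called in 1 genotype alone. Of 24430 union regions, 12129 (49.6%) had a peak in all 4 libraries, with a median length of 2922 bp. WT-only regions numbered 569 (2.33%) and KO-only regions 690 (2.82%), with median lengths of 1667 and 1593 bp. Most were weak calls. Their median score percentile was 21.6 for WT-only regions in the list of WT replicate 1. It was 16.8 for KO-only regions in the list of KO replicate 1. The crossed pairings gave 767 regions for WT replicate 1 with KO replicate 1 and 119 for WT replicate 2 with KO replicate 2, then 708 for WT replicate 1 with KO replicate 2 and 134 for WT replicate 2 with KO replicate 1. The split by genotype thus left 1259 regions on either side, against 886 and 842 in the crossed splits. Libraries also differed within a genotype, since 2571 regions were called in WT replicate 1 alone and 540 in WT replicate 2 alone. Without WT replicate 1, WT replicate 2, KO replicate 1 and KO replicate 2 in turn, the WT-only regions numbered 1196, 3244, 1232 and 871. The KO-only regions then numbered 3667, 990, 2092 and 1432.

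**Figure D1:**
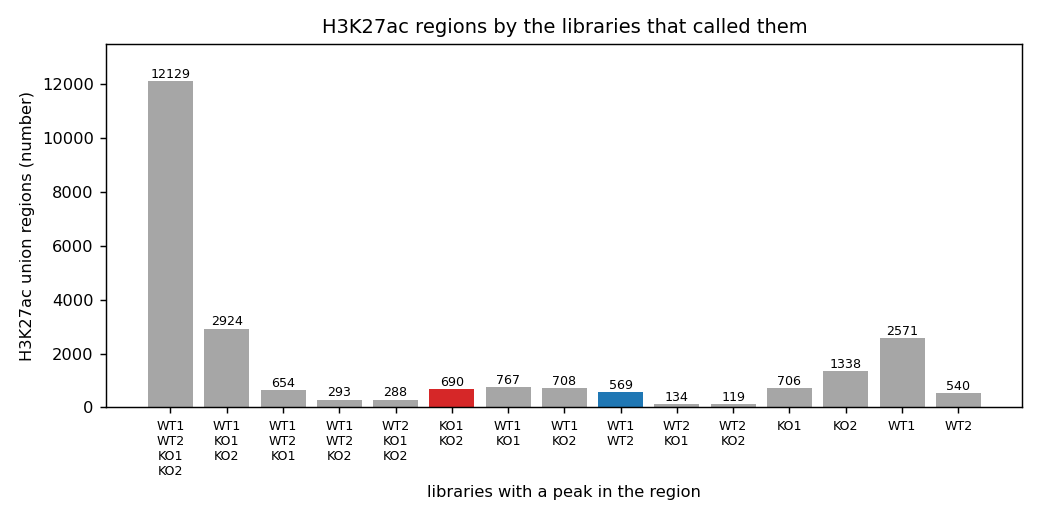
Number of H3K27ac union regions (y axis) for each combination of libraries with a peak in the region (x axis). The 12129 regions called in all 4 libraries form the tallest bar, and the 569 WT-only (blue) and 690 KO-only (red) regions are of similar number.

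The longest WT-only region spanned chromosome 10 from 122202935 to 122210151 (7217 bp) and overlapped a reproducible Smc1a site. A region on chromosome 14 from 16712465 to 16717013 (4549 bp) had scores of 567.81 and 279.68 in the WT lists, also held a Smc1a site, and lay 109110 bp from the nearest KO peak. The region on chromosome 5 from 137005869 to 137010412 (4544 bp) was covered over 4539 and 4502 bp by the WT libraries. It belonged to the cluster of chromosome 5 described with the longest clusters. The other long WT-only regions lay on chromosomes 17, 11, 19, 2 and 5 and were at least 4255 bp long. Of the 10 longest WT-only regions, 9 lay within 10000 bp of a KO peak, and 3 overlapped a Smc1a site.

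Among KO-only regions, a stretch of chromosome 2 from 169501731 to 169507919 (6189 bp) had scores of 1024.28 and 1044.24 in the KO lists, with the nearest WT peak 107582 bp away. A region of chromosome 9 from 42670212 to 42674846 (4635 bp) had scores of 784.76 and 2152.66 and lay 340723 bp from any WT peak. On chromosome 16, the region from 78197048 to 78201176 (4129 bp) held 2 Smc1a sites and lay 173909 bp from the nearest WT peak. Of the 10 longest KO-only regions, 3 lay within 10000 bp of a WT peak and 3 overlapped a Smc1a site.

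The longest KO-only region was of another size class. It spanned chromosome 14 from 54782908 to 54861130 (78223 bp), with 78214 bp covered in KO replicate 1 by 1 peak and 75656 bp in KO replicate 2 by 5 peaks, and no WT peak. It held 4 reproducible Smc1a sites. The Smc1a replicate 1 peak of 1 of them, from 54858285 to 54859262, had the highest score of its list (3163.02). The acetylated stretch that flanks the KO-only region was called in all 4 libraries, and a WT peak ended 6 bp before the KO-only region began. The single peak of KO replicate 1 had a score of 61.86, close to the lowest score of its list (50.01), while the best peak of KO replicate 2 reached 3100. Long stretches were also missing between libraries of 1 genotype, since 6 peaks of at least 20000 bp in WT replicate 1 were covered to under 10% by WT replicate 2. Outside this region WT replicate 2 lacked 12 of the 115 such peaks of the other libraries and KO replicate 1 lacked 1 of 140, while WT replicate 1 (0 of 124) and KO replicate 2 (0 of 155) lacked none. These are counts of peaks, not of separate stretches, since a stretch called in several libraries is counted once for each of its peaks.

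**Figure D2:**
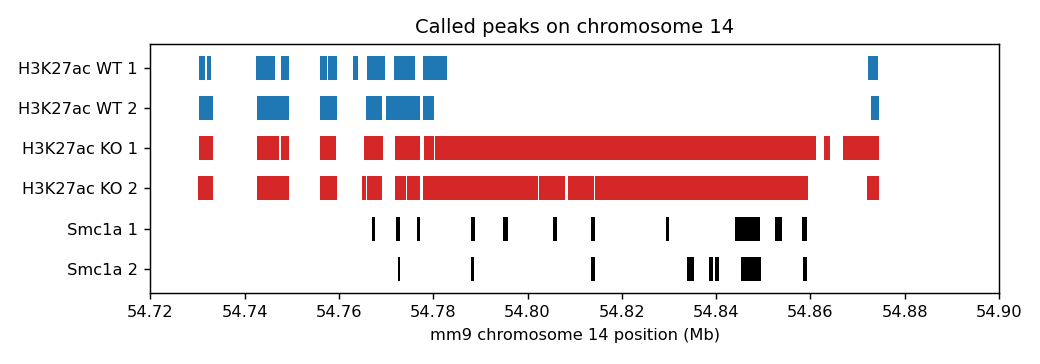
Called peaks along mm9 chromosome 14 (x axis, position in Mb) in the 4 H3K27ac and 2 Smc1a libraries (rows); each block is a called peak. Between 54782908 and 54861130 peaks cover 78214 bp in KO replicate 1 and 75656 bp in KO replicate 2, and neither WT library has a peak there.

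Smc1a was mapped in WT cells to place cohesin relative to acetylated chromatin. Of the peaks of replicate 1, 58.8% (95% interval 58.2 to 59.4) overlapped a peak of replicate 2, and of the peaks of replicate 2, 84.3% (83.7 to 84.8) overlapped a peak of replicate 1. The replicates shared 14848 reproducible sites. Of these, 3260 (22.0%, 95% interval 21.3 to 22.6) lay in an H3K27ac region called in both WT libraries, against 2.50% after circular shifts of the sites (middle 95% of shifts, 2.19 to 2.88). This was 8.77-fold above the shifted placement (permutation by circular shifts, p = 0.001, the smallest that 1000 shifts can give). The 5 longest reproducible sites all lay in such a region. They were on chromosome 6 from 71270846 to 71281829, chromosome 11 from 87566395 to 87575371, chromosome 8 from 123056621 to 123064833, chromosome 9 from 32516825 to 32524291 and chromosome 4 from 102659427 to 102666716.

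The overlap with Smc1a differed between acetylated regions called in WT and in KO cells. Of the 569 WT-only regions, 69 (12.1%, 95% interval 9.70 to 15.1) overlapped a reproducible Smc1a site, against 41 of the 690 KO-only regions (5.94%, 4.41 to 7.96). The difference was 6.18 percentage points (3.02 to 9.50; Fisher's exact test, p = 1.26e-04), and WT-only regions had the higher share on 16 of 20 chromosomes (sign-flip permutation test, p = 1.10e-04). Within 10000 bp of the region the contrast was wider in points, with a Smc1a site near 49.2% of WT-only and 29.3% of KO-only regions, higher on 20 of 20 chromosomes. The odds ratio was similar (2.34, against 2.18 for overlap). WT-only regions lay more often in clusters built from all 4 libraries alike (55.9%, against 23.0% of KO-only regions). The wider window can reach sites at neighbouring regions, and its contrast was not stratified by clustering. Regions called in all 4 libraries overlapped a Smc1a site in 20.3% of cases (19.6 to 21.1), above both classes (Fisher's exact test, p = 5.39e-07 against WT-only and 2.35e-25 against KO-only). They were also longer (median 2922 bp, against 1667 bp for WT-only and 1593 bp for KO-only regions), and this contrast was not matched on length. In the crossed pairings the pair that held WT replicate 2 had the higher share, with 11.8% for WT replicate 2 with KO replicate 2 against 7.56% for the pair of replicates 1 (Fisher's exact p = 0.146), and 8.96% for WT replicate 2 with KO replicate 1 against 6.36% for the other pair (Fisher's exact p = 0.263). Without WT replicate 2 the difference was 1.77 points (-0.162 to 3.46, Fisher's exact p = 0.0784; higher on 14 of 20 chromosomes, sign-flip permutation p = 0.0346), and with the sites of Smc1a replicate 1 alone it was 2.78 points (-1.19 to 6.84, Fisher's exact p = 0.180; 12 of 20 chromosomes, sign-flip permutation p = 0.111).

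**Figure D3:**
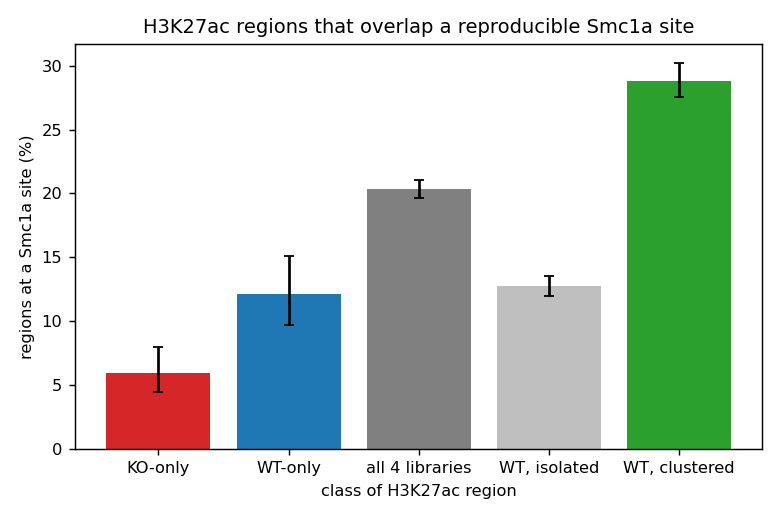
Share of H3K27ac regions that overlap a reproducible Smc1a site (y axis, %) by class of region (x axis); error bars are Wilson 95% intervals. WT-only regions (12.1%) lie above KO-only regions (5.94%), and clustered WT regions (28.8%) above isolated ones (12.7%).

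The title of the series concerns clusters of enhancers, so clustered and isolated acetylated regions were set side by side. Of 13937 regions called in both WT libraries, 4431 lay in 1060 clusters and 6402 were isolated. Clustered regions more often overlapped a Smc1a site, 28.8% (27.5 to 30.2) against 12.7% (11.9 to 13.6) of isolated ones, and did so on 20 of 20 chromosomes (Fisher's exact test, p = 2.42e-95). A reproducible Smc1a site lay on at least 1 region in 659 of the 1060 clusters (62.2%).

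Clustered WT regions were less often called in the KO libraries than isolated ones. Both KO libraries had a peak at 84.5% of clustered regions (83.4 to 85.5) and at 91.9% of isolated regions (91.2 to 92.6; Fisher's exact test, p = 3.90e-33). Neither KO library had a peak at 282 clustered regions (6.36%, 5.68 to 7.12) and at 164 isolated regions (2.56%, 2.20 to 2.98), an odds ratio of 2.59 (Fisher's exact test, p = 4.76e-22) with the same direction on 20 of 20 chromosomes. In each of the 1060 clusters at least 1 region had a KO peak, and 612 of 1060 clusters (57.7%) had every region called in both KO libraries. In the opposite direction, with clusters built from the KO libraries, 2.90% of clustered and 5.02% of isolated KO regions lacked a peak in both WT libraries (odds ratio 0.564, 95% interval 0.463 to 0.687). In the 4 crossed pairings the odds ratio was 1.06 and 1.21 where WT replicate 2 was among the libraries that called the regions, and 0.672 and 0.994 where it was not. Clustered regions were longer than isolated ones (medians of 3081 and 2323 bp), and after matching on length the share without a KO peak differed by 4.60 points, against 3.80 without matching. The unmatched difference was 7.14 points without WT replicate 1, 6.59 without WT replicate 2, and 5.99 where a shared peak had to cover at least 50%. That of regions called in both KO libraries was -12.5 points with the 50% overlap, against -7.46. With 1 KO library left, a region is either called in it or not, so these values are not like those from both libraries. The share without a KO peak then differed by 6.73 points without KO replicate 1 and by 4.53 without KO replicate 2.

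**Figure D4:**
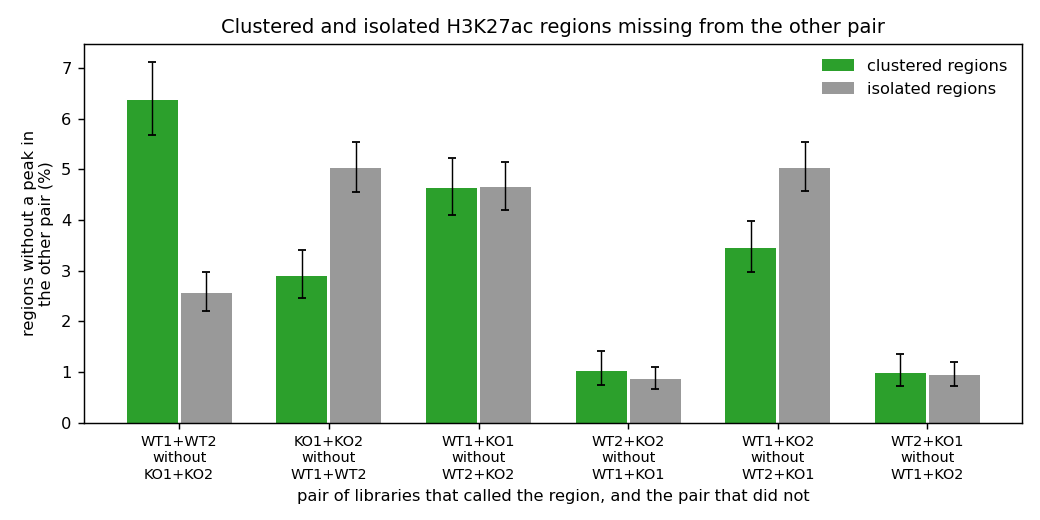
Share of regions called by 1 pair of libraries that lack a peak in both libraries of the other pair (y axis, %), for clustered (green) and isolated (grey) regions; each group of bars on the x axis is a pairing, and error bars are Wilson 95% intervals. The pairing of WT regions without a KO peak (6.36% and 2.56%) is the one with clustered regions well above isolated ones.

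The cluster with the greatest summed region length lay on chromosome 5 from 136854959 to 137051427 and held 21 regions. WT libraries covered 166538 and 169375 bp of it, and KO libraries 114064 and 83447 bp, with 12 of its regions called in both KO libraries and 3 in neither. On chromosome 10 from 122135765 to 122286922, a cluster of 16 regions was covered over 100227 and 92951 bp in WT and 63042 and 53563 bp in KO libraries, and 4 of its regions had no KO peak. A cluster of 17 regions on chromosome 17 from 52269946 to 52461057 was covered over 103470 and 127022 bp in WT and 93682 and 80867 bp in KO libraries. The cluster of chromosome 6 from 71247287 to 71361562, which holds the longest Smc1a site, differed least among the 10 longest, with 98476 and 101424 bp covered in WT and 96910 and 90081 bp in KO libraries. Coverage was lower in both KO than in both WT libraries in each of the 10 longest WT clusters, which were chosen on the WT libraries. It was also lower in each of the 10 longest clusters chosen on all 4 libraries alike, of which 8 start at the same base as those of the WT list. Over all 1591 clusters chosen in that way the balance was less one-sided, with both WT above both KO libraries in 484 (30.4%) and the reverse in 232 (14.6%). Scaled to the total covered length of each library, the counts were 455 and 321. A crossed pairing was more uneven at each step, with 553 against 43 for the pair of replicates 1 over the pair of replicates 2 before scaling, and 116 against 277 for WT replicate 1 with KO replicate 2 over the other pair after it.

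**Figure D5:**
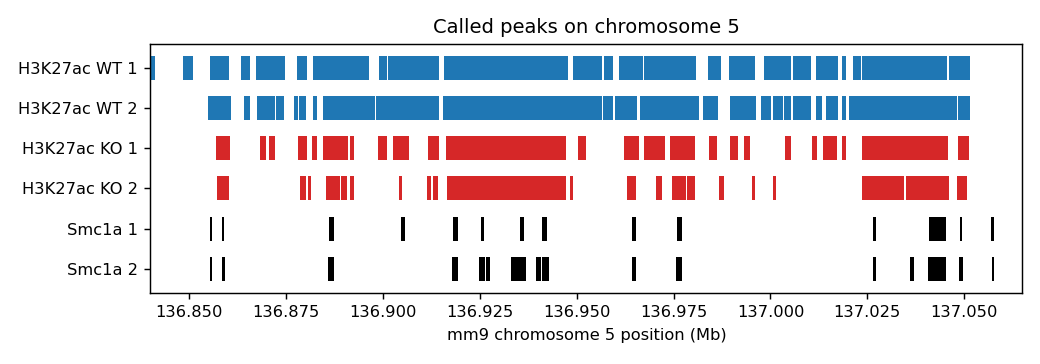
Called peaks along mm9 chromosome 5 (x axis, position in Mb) in the 4 H3K27ac and 2 Smc1a libraries (rows); each block is a called peak. Inside the cluster from 136854959 to 137051427 the KO libraries cover 114064 and 83447 bp, against 166538 and 169375 bp in the WT libraries.

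The 1591 clusters were built from regions called in at least 2 of the 4 libraries, whichever they were. They held 43.4% and 47.6% of the covered length of the WT libraries and 42.6% and 41.1% of that of the KO libraries (means 45.5 ± 2.93% and 41.8 ± 1.00%, SD, n = 2 each). Both WT values lay above both KO values, which gives the smallest p that 2 libraries against 2 allow (exact permutation test, p = 0.333). In length the clusters held 24.5 and 21.7 Mb of the WT and 22.4 and 19.6 Mb of the KO libraries, so KO replicate 1 lay above WT replicate 2 (exact permutation test, p = 0.667).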

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

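The alternative that leaves out the broad chromosome 14 region was chosen after seeing the data, and it changed no direction or call. Across 13 results and 106 alternatives, 89 kept their direction and side of the threshold or stayed within the range set for them. The 89 include alternatives that could not change a result. Leaving out a KO library cannot alter the Smc1a excess in clusters, and the replicate block cannot alter the mean differences. The Smc1a excess at WT-only regions lost the call of Fisher's exact test without WT replicate 2 and with Smc1a replicate 1 alone, while the test per chromosome kept it without WT replicate 2 (permutation p = 0.0346) and lost it in the other case (0.111), and over all left-out libraries the difference ran from 1.77 to 9.18 points. The excess of clustered WT regions without a KO peak, and the Smc1a excess in clusters, kept their direction and calls under every alternative run. Leaving out 1 library at a time moved the KO minus WT difference from -2099.5 to 4187.5 peaks and from -6.16 to 4.52 Mb, so its sign depended on single libraries. The Jaccard difference between and within genotypes ran from -0.0795 to 0.0314, and it was above 0 without KO replicate 2. The cause of these sign changes was not tested. The same step gave 871 to 3244 WT-only and 990 to 3667 KO-only regions, since fewer lists then have to agree. The share of Smc1a peaks shared by both replicates was 60.4% of replicate 1 and 86.7% of replicate 2 with the stricter threshold, and 73.4% of each with equal numbers of peaks. Equal numbers of peaks gave no peak number difference by construction, and the gene lists were not run. Taking the replicate number as a block left the differences at 1044 peaks and -0.820 Mb (exact sign-flip test, p = 1 for both) and the Jaccard difference at -0.0317, and the block cannot change the WT-only and KO-only counts. With 2 pairs no p under 0.5 can be reached. The numbers are not stated to mark shared litters. They do go with a property of the H3K27ac lists, since both lists numbered 2 held 4 peaks on chromosome Y and both numbered 1 held 0. Over all peaks, same-numbered libraries of different genotype overlapped little more (mean Jaccard index 0.680) than differently numbered ones (0.672). Read depth, which is unknown, limits how far a missing call can be read as lost acetylation.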

Other observations

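The matching of WT-only and KO-only regions on score percentile, the tests of very broad stretches at the chromosome 14 region, the scaling of neighbour shares to class size, the ratio of bridging odds, the distances, the clusters of regions called in all 4 libraries and the contrast of clustered regions with and without a Smc1a site were chosen only after results had been seen. Regions called in 1 genotype alone were grouped along the chromosomes. Of 245 pairs of adjacent genotype-specific regions within 100000 bp, 83.3% carried the same genotype, against 50.7% after shuffling genotypes within chromosomes (middle 95% of shuffles 44.5 to 56.7; permutation test, p = 1e-04, the smallest that the shuffles can give). In the crossed pairings, whose classes are of unequal size, the shares were 81.3% against 77.9% in shuffles (permutation test, p = 0.221) and 85.2% against 75.3% (permutation test, p = 0.0118). As a percent of the most that the class sizes allow, the excess was 66.0 for the genotypes (95% bootstrap interval over chromosomes 54.8 to 75.5), 15.0 (-14.5 to 43.3) for the pairs of equal number and 40.3 (21.4 to 60.7) for the other crossed pairing. The interval of the genotypes lies above that of the pairs of equal number but overlaps that of the other crossed pairing. The difference from that pairing was not itself tested, so grouping by genotype is not shown to exceed it.

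WT-only and KO-only regions also lay in different surroundings. The median distance to the nearest peak of the other genotype was 5589 bp for WT-only and 16510.5 bp for KO-only regions, shorter for WT-only regions on 19 of 20 chromosomes (sign-flip permutation test, p = 1e-05, the smallest it can give). In the crossed pairings the medians were 8688 bp for the pair of replicates 1 and 6254 bp for the pair of replicates 2 (permutation p = 0.0884), and 12329.5 bp for WT replicate 1 with KO replicate 2 and 4724.5 bp for WT replicate 2 with KO replicate 1 (permutation p = 0.00645). Distances thus also differed between pairs of libraries that mix the genotypes. Around the 779 clusters built only from regions called in all 4 libraries, 135 of 569 WT-only regions (23.7%, 95% interval 20.4 to 27.4) lay inside or within the stitching distance, against 34 of 690 KO-only regions (4.93%, 3.55 to 6.81; odds ratio 6.00, Fisher's exact test, p = 6.60e-23). In the crossed pairings the shares were 9.91% against 14.3% and 8.19% against 10.4%. Among clustered WT regions, those at a Smc1a site lacked a KO peak less often than those without one, 2.74% of 1278 against 7.83% of 3153 (odds ratio 0.331, Fisher's exact test, p = 1.59e-11). This contrast was not matched on region length or score. Smc1a sites inside WT acetylated regions had lower scores than other sites in replicate 1 (medians 175.8 and 293.3), a difference of -117.5 that lay outside the middle 95% of circular shifts (-22.5 to 54.2), so placement independent of Smc1a strength was not what the data showed.

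The hypothesis that acetylation spreads across cohesin sites once Rad21 is lost was tested at gaps of up to 3000 bp between acetylated regions. Gaps of the WT libraries that held a Smc1a site were bridged by both KO libraries in 3 of 132 cases, and gaps of the KO libraries that held one were bridged by both WT libraries in 8 of 119. The odds ratio was 0.323 (Fisher's exact test, p = 0.122), on 3 and 8 events. Gaps without a site showed a general asymmetry in the same direction, bridged in 173 of 4905 WT and 294 of 4203 KO gaps (odds ratio 0.486, Fisher's exact test, p = 9.20e-14). Relative to those gaps the contrast at sites was 0.664 (95% interval 0.170 to 2.60), which is too wide to decide on the hypothesis.

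The first pattern weighed is that clustered WT regions lacked a KO peak more often than isolated ones (odds ratio 2.59, 95% interval 2.12 to 3.15). Poorer reproducibility of clustered regions in any library was argued against by the crossed pairings, whose highest odds ratio was 1.21. Weaker scores in clusters were not found, since clustered regions had the higher median score percentile (56.6, against 47.2 for isolated ones). After matching on score percentile the difference was 4.20 points, against 3.80 without matching. Selection of clusters in the WT libraries was argued against by the opposite direction (0.564), although crossed pairings called without WT replicate 2 also gave low values (0.672 and 0.994), and dropped broad stretches by the odds ratio of 2.47 (2.01 to 3.02) away from very broad peaks. A hypothesis is that acetylated elements in clusters may lose the mark more often when Rad21 is deleted. The tests above bear on technical explanations and none tests the hypothesis itself, which was found on these 4 libraries, and a difference between the mice other than genotype was not tested. Clustered WT regions at a Smc1a site lacked a KO peak less often than those without one (2.74% against 7.83%), without matching on length or score.

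The second pattern is that WT-only regions overlapped Smc1a sites more often than KO-only regions, by 6.18 points. Region length (5.98 points after matching) was argued against as the whole cause. So was the larger share of WT-only regions in clusters (stratified odds ratio 2.09, 95% interval 1.37 to 3.20). At the 7424 sites with the highest replicate 1 scores, the ratio of shares was 2.08 (36 WT-only and 21 KO-only regions, Fisher's exact p = 0.00620). This argued against weak Smc1a calls as the whole cause, among sites called in both Smc1a replicates. With the sites of replicate 1 alone the shares were 16.7% of WT-only and 13.9% of KO-only regions. They were 16.0% and 6.81% with those of replicate 2 alone, so the size of the excess depended on the Smc1a list. The comparison at high-scoring sites cannot exclude a Smc1a signal that follows WT acetylation at strong sites, since KO-only regions had no call in WT cells. Selection of stronger regions by the short list of WT replicate 2 cannot be told apart from genotype, because the difference was 5.45 points after matching on score percentile but 1.77 points without that library, and the crossed pairs that held it also had the higher shares (11.8% against 7.56% and 8.96% against 6.36%). Smc1a was mapped in WT cells alone, so cohesin sites of KO cells were not analysed here.

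The third pattern is the stretch of chromosome 14 from 54782908 to 54861130, called in both KO and in no WT library. A candidate explanation is that the peak caller dropped a very broad stretch, since 6 peaks of at least 20000 bp in WT replicate 1 were covered to under 10% by WT replicate 2. WT replicate 1 also lacks the stretch, yet it lacked 0 of 124 such peaks of the other libraries elsewhere. Without this region, 2 of 8 peaks of 40000 bp or more (25%) had a score of 3100 or more, against 71.8% of 1167 peaks of 10000 to 20000 bp (exact test stratified by list, p = 0.00904), with the lower share in each of the 3 lists that held such peaks (exact p of 0.123, 0.177 and 0.197). A dropped stretch and a gain of acetylation in KO cells cannot be told apart from these lists, and reads would be needed to decide. Explanations other than these were not weighed, and the genes of the stretch were not identified.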
